A study of Mus musculus with 17 samples.

How the data were processed

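RNA was extracted with TRIzol and a column with DNase treatment from whole placentas collected at embryonic day 17.5 and frozen in liquid nitrogen, and dual-indexed libraries were made with the TruSeq stranded mRNA kit, per the labels' protocols. The values used are the raw counts per gene that the authors deposited for 17 libraries, as whole numbers with no scaling. The file lists an Ensembl gene ID, a gene name, a length and 1 column per library, per the file headers. Trimmomatic 0.33, FastQC, HISAT2, edgeR and genome build GRCm39 are named, per the submitters' processing notes, without their order or settings. The counting tool, its strand setting and the annotation release are not given in the sources used here. The start and end listed for a gene cover 1 exon only (for 59.4% of genes that interval is shorter than the listed length), so positions are given as that exon's. The reference table at hand follows another build, GRCm38.p6, and was used only to match older gene symbols.

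The 17 libraries form 4 groups by sex and genotype: 5 female controls, 4 female knockouts, 4 male controls and 4 male knockouts. The replicate numbers only name samples, since they pair no libraries in the labels. No 2 libraries of the same group were copies of each other: within groups, chi-square per degree of freedom ran from 19.4 to 151, and Pearson r from 0.9789 to 0.9926. Libraries of different groups were not compared in this check. Each library held 45.89 to 65.76 M counts. The floor of 3 counts stands for 0.0636 CPM in the female library with the smallest normalised size. Of the scarce genes named in the text, Gm17182 stood at 0.02542 CPM in male knockouts and Gm19784 at 0.009911 CPM in female knockouts, under that floor, so the size of their changes is not known. Reads carry no molecular identifiers, so the floor covers counting error only.

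Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 19591 of 57010 genes and 99.96% of all counts, and 19432 genes had 0 counts in every library. Counts were scaled by TMM and fitted with edgeR 4.0.16 in R 4.3.3, with a robust quasi-likelihood model of the 4 groups over all 17 libraries. From it came 6 contrasts: knockout against control in females, in males and averaged over both, the sex-by-genotype term (the male change minus the female change), and male against female in controls and in knockouts. P-values were adjusted by Benjamini-Hochberg over all tested genes within a contrast, and a gene was called at an adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of the quasi-likelihood F, an approximation. Values per library are TMM-normalised CPM computed here, with SD between libraries.

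Before the data were examined, the design, the contrasts, the alternatives and 40 gene lists (23 pathways, 15 cell types and 2 for the sex chromosomes) were fixed, as was the rule for naming genes. That rule takes, per contrast, up to 8 called genes with the largest rise and 8 with the largest fall at a mean of at least 1 CPM, every called member of a list, the mitochondrial calcium genes whether called or not, the Y and X lists in the sex contrasts, and the 10 genes with the smallest p where fewer than 10 were called. Of 759 symbols on the lists, 2 were not matched to the file, 13 were matched through an older symbol, and 11 were matched but had too few counts to be tested. Each list with at least 4 tested members was compared with the other genes by camera (limma 3.58.1, preset correlation 0.01, log2 CPM with a prior count of 2), again with a correlation estimated per list, and by fry, which asks whether the genes of a list move on balance in 1 direction and makes no comparison with other genes. Adjustment was over the 40 lists of a contrast. Within each list, p-values of the members were also adjusted over the list alone. A score per library is the mean log2 CPM of a list's tested members, and 41 scores, the zone balance included, were compared by two-sided exact permutation tests. The zone balance, added after seeing the data, is the mean of the scores of both syncytiotrophoblast layers minus the mean of the scores of spongiotrophoblast with glycogen trophoblast and of parietal giant cells.

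The alternatives were DESeq2 1.42.0, limma-voom with quality weights, RLE and upper-quartile scaling, no count filter and a stricter one (1 CPM in 4 libraries), a fit on only the groups compared, the decidua or the yolk sac score as a covariate, the replicate number as a block, and each library left out in turn. Removal of each library's trend with gene length and the zone balance score as a covariate were added after seeing the data. The model was tested on simulated counts drawn from the real means with 200 genes changed, all of them with a mean of at least 1 CPM. At 2-fold, 80.6% of changed genes were recovered in the female comparison (19351 genes) and 85.1% in the male (19375 genes), and with no gene changed 0 were called in either. The simulation holds no correlation between genes. All 17 libraries were used, and no column was left out.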

Results

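Whole mouse placentas taken at embryonic day 17.5 were profiled by sequencing of polyadenylated RNA, in 17 libraries: 5 from female controls, 4 from female knockouts, 4 from male controls and 4 from male knockouts. In the knockouts, the Cyp19-Cre recombinase, which is active in trophoblast, acts on a floxed Mcu gene. Mcu encodes the pore of the mitochondrial calcium uniporter, the channel through which mitochondria take up calcium. Each library held 45.89 to 65.76 M counts (mean 53.61 ± 5.295 M, SD, n = 17), with group means of 57.42 M in female controls, 53.82 M in female knockouts, 52.2 M in male controls and 50.06 M in male knockouts. Of 57010 genes in the table, 19591 had enough counts to be tested. The most abundant transcript in 16 of the 17 libraries was that of Prl3b1, a placental lactogen, and it took 1.91% to 3.23% of the counts. Replicate libraries correlated with Pearson r between 0.9789 and 0.9926 over genes. The labels do not say which placentas came from 1 litter. Placentas that share a litter would not be independent samples, and the p-values may then overstate the replication.

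Mcu itself (ENSMUSG00000009647, GRCm39 chromosome 10, with 1 exon listed at 59282806 to 59284680) was lower in the knockouts of both sexes. Female controls carried 36.7, 37.4, 36.71, 38.45 and 41.1 CPM (counts scaled to library size) of Mcu in replicates 1 to 5, and female knockouts 27.28, 18.82, 28.4 and 26.13 CPM in replicates 1 to 4. The mean was 38.07 ± 1.84 CPM (SD, n = 5) in female controls and 25.16 ± 4.32 CPM (SD, n = 4) in female knockouts, or 66.1% of control. Male controls carried 38.71, 40.91, 38.3 and 44.63 CPM and male knockouts 21.76, 35.51, 26.96 and 22.19 CPM in replicates 1 to 4. The male means were 40.64 ± 2.9 CPM (SD, n = 4) and 26.61 ± 6.39 CPM (SD, n = 4), or 65.5% of control. All 8 knockout libraries lay below all 9 control libraries, although male knockout replicate 2, at 35.51 CPM, lay close to the lowest control. The counts cover all annotated exons of the gene, and the sources used here do not name the deleted part, so any transcript that lacks it is still counted.

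In a two-sided exact permutation test, Mcu differed between genotypes with p = 0.0159 in females (n = 5 and 4) and p = 0.0286 in males (n = 4 and 4), in each case the smallest p that so few samples allow. In edgeR's quasi-likelihood test the log2 fold change was -0.60 (SE 0.133) in females and -0.61 (SE 0.139) in males. Mcu fell in both sexes when the p-values were adjusted over the list alone, that is, over 14 genes of mitochondrial calcium handling (adjusted p = 0.00438 in females and 0.00548 in males). Adjusted over all 19591 genes, it did not pass in either sex (adjusted p = 0.321 and 1). In females it passed in 2 of 28 alternative settings, DESeq2 (adjusted p = 0.0299) and without female knockout replicate 1 (log2 fold change -0.65, adjusted p = 0.0315), over a range from 0.0299 to 0.984. In males it passed in 0 of 28, with adjusted p from 0.166 to 1.

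**Figure D1:**
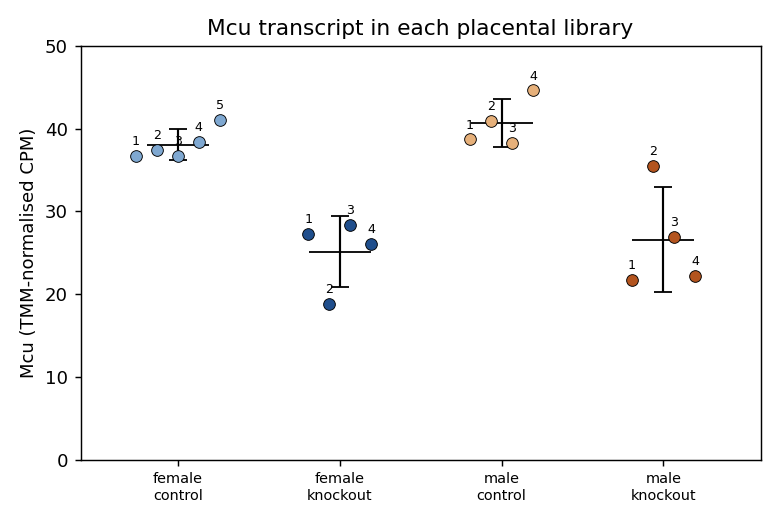
Mcu in each library, in TMM-normalised CPM on a linear axis, by sex and genotype. Each point is a library, numbered by its replicate, and the bar gives the mean ± SD of its group. The 8 knockouts lie between 18.82 and 35.51 CPM and the 9 controls between 36.7 and 44.63 CPM.

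The comparison of female knockouts with female controls asks how loss of the uniporter in trophoblast alters the female placenta. Transcripts of endothelium and of the layers that exchange nutrients with maternal blood were lower in the female knockouts. The endothelial list is named for the fetal vessels, but whole placenta also holds maternal tissue. Which share of these transcripts is fetal was not measured. All 16 tested markers of fetal endothelium were lower (median log2 fold change -0.50), as were 19 of 25 angiogenesis genes (median -0.33), all 7 markers of syncytiotrophoblast layer I (median -0.38), all 8 of layer II (median -0.55), and 26 of 28 genes for nutrient transporters (median -0.33). Imprinted genes were lower in 26 of 32 cases (median -0.17) and erythroid genes in 10 of 13 (median -0.85). Against the other genes, camera with a preset correlation gave adjusted p = 2.4e-08 for fetal endothelium, 4.57e-05 for angiogenesis, 0.000129 and 0.00251 for the syncytiotrophoblast layers, 8.75e-08 for nutrient transporters, 6.42e-06 for imprinted genes and 1.53e-05 for erythroid genes. With an estimated correlation none of these passed (adjusted p = 0.442 for fetal endothelium, angiogenesis, layer I, nutrient transporters and imprinted genes, 0.546 for layer II and 0.421 for erythroid genes). Nor are the lists all separate: 4 of 16 endothelial and 7 of 25 angiogenesis genes stand on another list too. So do 3 of 7 layer I, 3 of 8 layer II, 6 of 28 nutrient transporter and 8 of 32 imprinted genes.

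No gene in these groups passed over all genes in edgeR (smallest adjusted p in females 0.321). Adjustment over the list alone, used next, does not count the other lists. By it, 3 endothelial genes fell in females: Pecam1, an adhesion molecule of endothelial junctions, from 142.9 ± 11.1 to 99.2 ± 33 CPM (log2 fold change -0.53, SE 0.16), Cd34 (-0.60, SE 0.166) and the endothelial transcription factor Erg (-0.75, SE 0.228). In layer I, Slc1a5, a glutamine transporter (-0.76, SE 0.234), and Stra6, the retinol-binding protein receptor (-0.38, SE 0.124), fell. Among the nutrient transporters, Slc3a2, the heavy chain of several amino acid transporters, fell from 519.3 ± 59.7 to 379.6 ± 56.4 CPM (-0.45, SE 0.11). The erythroid list had 6 members that fell, among them Hba-a1 (946.1 ± 160 to 469.3 ± 139 CPM, log2 fold change -1.01, SE 0.23), Alas2, which starts haem synthesis (-0.90, SE 0.216), and Gypa, glycophorin A (-1.06, SE 0.215). Hba-a1 and Hba-a2 are near-identical copies, and reads from one can be counted on the other. Whole placenta holds blood that dissection can leave in unequal amounts, and this was not tested for the erythroid genes. Members that did not pass over their list include Igf2, which encodes a fetal growth factor (131.1 ± 18.9 and 86.09 ± 24.5 CPM, -0.61, SE 0.183), and Gjb2, the gap junction channel between the syncytial layers (644.6 ± 138 and 388.3 ± 162 CPM, -0.73, SE 0.277). The list members given as examples here and in later paragraphs were chosen after their values were seen.

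Transcripts of the hormone-producing junctional zone of the female placenta were higher in knockouts. Of 24 tested placental prolactins and lactogens, 23 were higher (median log2 fold change 0.40), as were 20 of 21 markers of spongiotrophoblast and glycogen trophoblast (median 0.22) and all 8 of parietal trophoblast giant cells (median 0.53). Prl3b1 stood at 21340 ± 1390 CPM in female controls and 28930 ± 6840 CPM in female knockouts (0.44, SE 0.157). It is on the prolactin and the sinusoidal giant cell lists, but not on the spongiotrophoblast or the parietal giant cell list. No single member of the prolactin, spongiotrophoblast or parietal giant cell list passed, over its list or over all genes. Endoplasmic reticulum chaperones, which serve secreted proteins, were higher in 17 of 19 cases (median 0.20), with Xbp1 at 0.22 (SE 0.071). Camera with a preset correlation gave adjusted p = 3.28e-05 for the prolactins, 0.0102 for spongiotrophoblast, 0.0109 for parietal giant cells and 0.0022 for the chaperones. With an estimated correlation the adjusted p was 0.528, 0.563, 0.546 and 0.546. The call for spongiotrophoblast ended without female knockout replicate 3 (adjusted p = 0.121) or replicate 4 (0.114), and that for parietal giant cells without female knockout replicate 4 (0.0582). These lists share members: 9 of the 21 spongiotrophoblast genes and 5 of the 8 parietal giant cell genes stand on another list as well.

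Genes of protein synthesis moved as a block in female knockouts: 44 of 45 ribosomal protein genes were higher, with a median log2 fold change of 0.28. When adjusted over the list alone 39 of them rose, although none passed over all genes in edgeR. Examples are Rps9 (190.1 to 250.5 CPM, 0.40, SE 0.101), Rpl38 (0.33, SE 0.0751) and Rps6 (303.6 to 368.8 CPM, 0.28, SE 0.0657). Many ribosomal protein genes have processed pseudogenes, whose sequence can share reads with them. Of 74 nuclear genes for oxidative phosphorylation, 64 were higher (median 0.12), among them Uqcrh (0.25, SE 0.0735) and Ndufa6 (0.25, SE 0.0779). In contrast, 12 of the 13 mitochondrially encoded transcripts were lower (median -0.22), with mt-Nd5 at 1553 ± 209 CPM in controls and 1149 ± 142 CPM in knockouts (-0.43, SE 0.143). Camera with a preset correlation gave adjusted p = 5.86e-23 for ribosomal proteins, 1.14e-06 for oxidative phosphorylation and 0.0172 for the mitochondrially encoded list, and with an estimated correlation the adjusted p was 0.442, 0.546 and 0.546. The mitochondrially encoded call ended without female knockout replicate 2 (0.289) or 3 (0.0722). The libraries were selected for polyadenylated RNA, and mitochondrial transcripts are only partly captured by that step. With each library's trend with gene length removed, the oxidative phosphorylation median in log2 CPM went from 0.109 to 0.0552.

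Among the other calcium-handling genes of the mitochondrion, no change passed the test in females. The gatekeepers Micu1, Micu2 and Micu3 had log2 fold changes of 0.07, 0.11 and 0.12 in females, the essential subunit Smdt1 0.16, the assembly factor Mcur1 0.12, and the paralog Mcub -0.01, all with unadjusted p above 0.05 in edgeR. The sodium and calcium exchanger Slc8b1 (0.02), Letm1 (0.01), Ghitm (-0.09), Slc25a23 (-0.12), Vdac1 (-0.10), Vdac2 (0.08) and Vdac3 (0.00) also had unadjusted p above 0.05. Over the whole list in females the median (0.02) and the mean (-0.02) differ in sign, camera's direction was down, and its adjusted p was 0.976. The sign of that median changed with the scaling, as did that of the labyrinth progenitor list, both near 0.

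Further lists that camera called in females were inflammation (median 0.29, adjusted p = 0.0119), the interferon response (0.19, 0.0156) and glycolysis (0.08, 0.0411), all higher in knockouts, and cell cycle (-0.16, 0.0169), uterine smooth muscle (-0.30, 0.0203), fatty acid handling (-0.02, 0.0338) and fetal stroma and pericytes (-0.23, 0.0341), all lower. None passed with an estimated correlation (adjusted p from 0.442 for inflammation to 0.658 for the interferon response), and for each of them leaving out 1 library ended the call. That library was female knockout replicate 1 for inflammation (adjusted p = 0.0768), female control replicate 1, female knockout replicate 2 or 4 for the interferon response (0.261, 0.0685 and 0.191), female knockout replicate 2 or 4 for cell cycle (0.249 and 0.0582), and female control replicate 2 or female knockout replicate 4 for smooth muscle (0.097 and 0.283). Glycolysis was lost without female knockout replicate 1 or 4 (0.439 and 0.106), female control replicate 3 or 5 (0.0602 and 0.114) or male control replicate 2 (0.0536). Fatty acid handling was lost without female control replicate 1 or female knockout replicate 3 or 4 (0.118, 0.168 and 0.114), and fetal stroma without female control replicate 1, 2 or 3 or female knockout replicate 3 or 4 (0.0541, 0.106, 0.0561, 0.0569 and 0.144). Lists that were not called in females were the TCA cycle (median -0.03), insulin and IGF signalling (-0.01), the integrated stress response (0.13), mitochondrial quality control (0.05), antioxidant genes (0.08), the hypoxia response (0.18), steroidogenesis (0.06), immediate early genes (0.02), extracellular matrix (0.05), sinusoidal giant cells (0.08), labyrinth progenitors (0.00), maternal decidua (0.32), uterine natural killer cells (0.20), yolk sac (-0.01), macrophages (0.14), neutrophils and platelets (-0.05), and the X list (-0.02).

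**Figure D2:**
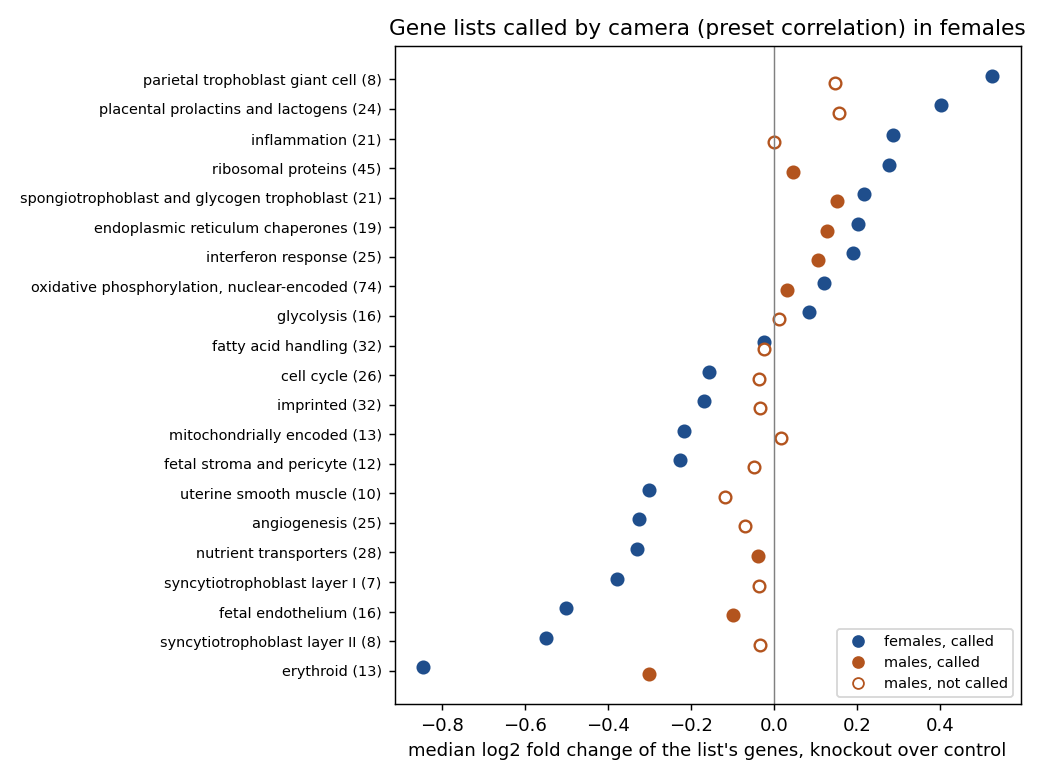
Median log2 fold change of each gene list, knockout over control, in females and in males, with filled symbols for lists called by camera at a preset correlation and open symbols for the others. Over the 21 lists shown, the female medians run from -0.85 for erythroid genes to 0.53 for parietal giant cells, and the male medians from -0.30 for erythroid genes to 0.16 for prolactins.

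No single gene passed over all genes in females (0 of 19591 by edgeR, smallest adjusted p = 0.321), although 2796 genes had an unadjusted p under 0.05 (1400 higher and 1396 lower), against 980 that chance would give. The genes with the smallest p were the noncoding 2410006H16Rik (28.04 ± 2.87 to 41.76 ± 7.99 CPM, log2 fold change 0.57, SE 0.107), the protocadherin Pcdh1 (33.58 ± 0.625 to 24.07 ± 3.77 CPM, -0.48, SE 0.0945), Gypa (6.23 ± 1.61 to 2.97 ± 0.965 CPM) and Mpl, the thrombopoietin receptor (1.89 ± 0.153 to 1.04 ± 0.35 CPM, -0.85, SE 0.184). They were followed by Metrnl (0.38), Svip (-0.77), Vsir (0.34), Mcu, Ube2l6 (-0.62) and Smarca2 (-0.30). DESeq2 called 33 genes in females, 10 higher and 23 lower, all with the same sign and an unadjusted p under 0.05 in edgeR. Among them were Gypa, Hba-a1, Alas2, Mpl, Mcu and Slc3a2 on the lower side and Rps6, Rpl21 and Rpl38 on the higher.

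These female counts turned on single libraries. Without female knockout replicate 1, edgeR called 1083 genes (373 higher and 710 lower), where 19591 were tested over all libraries. Of the 1083, 1080 had the same sign in the fit on all 17 libraries, and all 33 of the DESeq2 genes were among them. These fits share all libraries but 1, so that agreement was largely fixed in advance. On the lower side, the 1083 genes took in 10 of 16 endothelial genes (Plvap -1.09, Robo4 -1.05, Tek -0.99), 9 of 25 angiogenesis genes, 6 of 28 nutrient transporters (Slc2a1 -0.60) and 7 of 32 imprinted genes (Igf2 -0.77, Dlk1 -0.74). On the higher side were 29 of 45 ribosomal proteins, 6 of 74 oxidative phosphorylation genes and 5 of 24 prolactins (Prl3b1 0.59). Other lists described above had few called members. Those were 1 of 7 layer I and 1 of 8 layer II genes, both lower, and 2 of 21 spongiotrophoblast genes, both higher. Of the 8 parietal giant cell and 13 mitochondrially encoded genes, 0 were called. Without female control replicate 3, 1 gene passed, Gm19784 (lower, adjusted p = 0.0434), which over all libraries stood at 0.4153 ± 0.294 CPM in female controls and at 0.009911 CPM in female knockouts, under the floor of 3 counts, so no fold is given. The mean log2 CPM of fetal endothelium genes was 5.393 in female knockout replicate 1, within the female control range of 5.156 to 5.501, and 4.316, 4.982 and 4.613 in replicates 2 to 4, while its Mcu, at 27.28 CPM, lay among the knockouts. The maternal decidua score of female knockout replicate 1, at 5.279, was the highest of all 17 libraries. Of the 40 lists, 21 were called in all libraries (9 higher, 12 lower), and 11 of them were called whichever single library was left out. The lowest count was 13, without female knockout replicate 4.

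Scores per library, taken as the mean log2 CPM of a list, were compared by exact permutation tests on samples instead of genes. Their sign was that of the list median for each of the 21 lists called in females and the 12 called in males. In females it was opposite for 7 lists that were not called: mitochondrial calcium, steroidogenesis, extracellular matrix, labyrinth progenitors, uterine natural killer cells, yolk sac and the X list. In females (n = 5 and 4) the erythroid score was lower by 0.57 on the log2 scale in knockouts than in controls, with exact p = 0.0159. The differences were -0.50 for syncytiotrophoblast layer I, -0.27 for imprinted genes and 0.25 for ribosomal proteins, each with exact p = 0.0317, and -0.36 for nutrient transporters with exact p = 0.0476. Fetal endothelium (-0.492, exact p = 0.0794), layer II (-0.534, 0.0635), angiogenesis (-0.309, 0.0952) and prolactins (0.374, 0.0952) stayed above 0.05. So did parietal giant cells (0.455, exact p = 0.127) and spongiotrophoblast (0.2, 0.302). With the median of the list as the score, the differences were -1.07 for erythroid genes and -0.373 for imprinted genes (exact p = 0.0317 each), 0.261 for ribosomal proteins (0.0635), -0.321 for nutrient transporters (0.0794) and -0.228 for layer I (0.175). None of 41 scores passed adjustment (smallest adjusted p = 0.325). The zone balance score, which sets the syncytiotrophoblast lists against those of the junctional zone, was lower by 0.84 in female knockouts (exact p = 0.0794) and by 0.28 in male knockouts (exact p = 0.543).

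**Figure D3:**
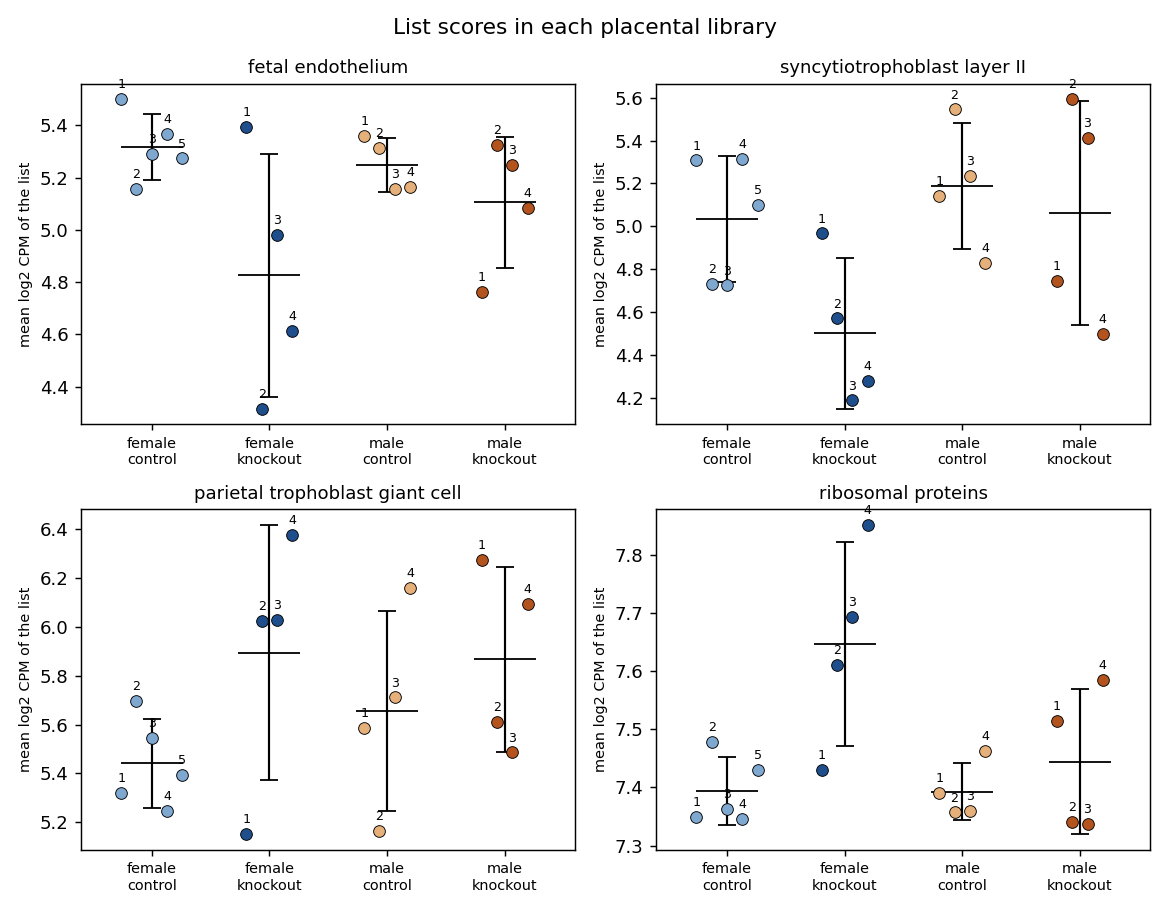
Scores per library (mean log2 CPM of a list's tested genes) by sex and genotype, 1 point per library numbered by its replicate, with the mean ± SD of each group as a bar. Female knockout replicate 1 sits at 5.393 for fetal endothelium, with the controls, and replicates 2 to 4 sit between 4.316 and 4.982.

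In males, the comparison of knockouts with controls asks the same question of the male placenta. Endoplasmic reticulum chaperones (median log2 fold change 0.13, camera adjusted p = 0.00322), the interferon response (0.11, 0.00322), spongiotrophoblast and glycogen trophoblast (0.15, 0.0198), ribosomal proteins (0.05, 0.0121), oxidative phosphorylation (0.03, 0.0171) and the Y-linked list (0.09, 0.0237) were higher in male knockouts. Fetal endothelium (-0.10, 0.0139), maternal decidua (-0.14, 0.0171), immediate early genes (-0.11, 0.0171), nutrient transporters (-0.04, 0.0465) and erythroid genes (-0.30, 0.0465) were lower. The largest median was that of yolk sac endoderm, where all 17 tested genes were lower (-1.33, adjusted p = 0.000103): Afp, alpha-fetoprotein, stood at 738.9 ± 833 CPM in male controls and 220 ± 160 CPM in male knockouts, and Apoa1 at 181.7 ± 209 and 52.66 ± 37.6 CPM. All 12 lists had an adjusted p of 0.883 with an estimated correlation. The yolk sac score did not differ in an exact permutation test (difference -0.97, exact p = 0.343, n = 4 and 4), its genes varied widely within groups, and the call ended without male control replicate 3 (0.123). Each of the other 11 calls also ended when some single library was left out, and the count of 12 fell to 1 without male control replicate 2, 3 without male knockout replicate 4, 6 without male control replicate 1 and 7 without male knockout replicate 1.

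The male gene with the smallest p was Eif2s3y (ENSMUSG00000069049), the Y-linked copy of a translation initiation factor subunit. It stood at 20.25 ± 4.72 CPM in male controls and 35.77 ± 3.09 CPM in male knockouts (log2 fold change 0.82, SE 0.152, adjusted p = 1), and its neighbour on the Y chromosome Gm29650 stood at 0.9329 and 1.797 CPM (0.94, SE 0.22). Ddx3y (38.61 and 40.18 CPM), Kdm5d (10.44 and 11.36 CPM) and Uty (9.503 and 9.415 CPM) were close between genotypes. After these and Mcu came Gm17182 (lower, with male knockouts at 0.02542 CPM, under the floor of 3 counts), 1810024B03Rik (-0.55), Tssk3 (-0.92), Car7 (0.83), Gm7816 (-0.62), Ltb (0.94) and Gm8818 (-1.39). In edgeR, 0 genes passed in males, with 394 at an unadjusted p under 0.05 against 980 by chance, and DESeq2 called 0. Limma-voom with sample quality weights called 2, Eif2s3y (0.84) and Gm29650 (1.01), both with adjusted p = 0.0194, and over all 28 alternative settings their adjusted p ran from 0.0194 to 1. The strand setting of the counting is not given, so reads of overlapping antisense transcripts cannot be told from those of the genes named.

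The series asks whether the sexes respond differently, which the sex-by-genotype term tests directly. It is the male change minus the female change. Ribosomal proteins (median -0.23, camera adjusted p = 1.49e-15) and inflammation genes (-0.21, 0.000783) had a lower knockout effect in males than in females. Fetal endothelium (0.36, 0.00023), angiogenesis (0.24, 0.000263), nutrient transporters (0.23, 0.00023), imprinted genes (0.15, 0.00023), syncytiotrophoblast layer I (0.44, 0.00378) and erythroid genes (0.50, 0.00339) had a higher one, that is, their levels in male knockouts lay nearer to control. These 8 lists kept their calls whichever library was left out, while 7 further lists did not. With an estimated correlation none of the 15 lists passed (adjusted p from 0.609 up). For these lists, exact permutation tests of the term on library scores gave p from 0.0791 (inflammation) to 0.499 (oxidative phosphorylation). Mcu had the same log2 fold change in both sexes within its error (difference -0.01, SE 0.191, adjusted p = 0.998 in edgeR).

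No gene passed the sex-by-genotype test in edgeR (0, smallest adjusted p = 0.985) or in DESeq2 (0), and 628 had an unadjusted p under 0.05, 258 higher and 370 lower, against 980 by chance. The smallest p values belonged to the unnamed ENSMUSG00000120678 (2.53, SE 0.59), Dhcr7, the last enzyme of cholesterol synthesis (-0.46, SE 0.117), Gm11826 (-0.95), Gm13408 (-0.66), Dusp2 (0.83), Elk4 (-0.34), Zfp182 (-0.58), Tssk3 (-1.19), Gm10275 (-0.52) and Rhox2a (3.37, SE 0.927). Over all genes, the female and male log2 fold changes correlated weakly (Pearson r = 0.185, Spearman rho = 0.246, across genes, which are not independent replicates). Of the 2796 genes with an unadjusted p under 0.05 in females, 2098 (75%) had the same sign in males, against 61.1% of all genes, and 40 had an unadjusted p under 0.05 with that sign. Of the 21 lists called in females, 20 had the same camera direction in males and 8 were called there.

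The average of both sexes is the mean of the female and male changes, and 8 of the 10 lists named here were also called in the sex-by-genotype term. In it, ribosomal proteins were higher (median log2 fold change 0.16, camera adjusted p = 8.64e-19), and 27 of 45 rose when adjusted over the list alone. Erythroid genes were lower (-0.52, 2.58e-05), with 7 of 13 members that fell over the list alone, as were fetal endothelium (-0.34, 3.57e-08), nutrient transporters (-0.20, 5.66e-07), syncytiotrophoblast layers I and II (-0.21 and -0.30, adjusted p = 0.000701 and 0.00662) and imprinted genes (-0.11, 0.000194), while prolactins (0.27, 7.49e-05), parietal giant cells (0.33, 0.00782) and chaperones (0.15, 8.97e-05) were higher. With an estimated correlation the adjusted p was 0.457 for erythroid genes and 0.56 for the others named, and layer II lost its call without male knockout replicate 4 (0.0618). Camera called 18 lists. In edgeR, 0 genes passed over all genes, with 1959 at an unadjusted p under 0.05 (1079 higher and 880 lower). Mcu came first (-0.60, SE 0.0959, adjusted p = 0.159, and 0.000114 adjusted over the list alone), followed by Svip (-0.59), Mpl (-0.62), Pxt1 (0.68), Pcdh1 (-0.30), Gm17182 (lower), Vsir (0.24), Angel1 (0.33), Slc34a2 (-0.44) and H2az2 (0.19). DESeq2 called 2 genes, Mcu (adjusted p = 0.000123) and Mpl (0.0267), and without male knockout replicate 2 edgeR called 1, Mcu (-0.69, adjusted p = 0.00419). Over the 27 alternatives Mcu's adjusted p ran from 0.000123 to 0.999, and Mpl's from 0.0267 to 0.999.

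Male and female controls were compared to check the sex labels and to give the baseline difference. In edgeR 10 genes differed, all on the sex chromosomes, with 847 at an unadjusted p under 0.05. Of these, 5 are on the Y chromosome: Ddx3y, Eif2s3y, Kdm5d, Uty and Gm29650. The first, Ddx3y, stood at 38.61 CPM in male controls and had 0 counts in each female library, and Eif2s3y had 1 count in 1 female library. Against a floor of 3 counts in the female library with the smallest normalised size, the male library with the lowest level was at least 528-fold higher for Ddx3y, 142-fold for Kdm5d, 132-fold for Uty and 11.7-fold for Gm29650. On the X chromosome, Xist, the noncoding RNA of X inactivation, was lower in males (536.5 ± 66.2 CPM in female and 53.04 ± 15.3 CPM in male controls, log2 fold change -3.34, SE 0.182), as were Ogt (-0.70, SE 0.0772), Taf1 (-0.60, SE 0.0653), Pin4 (-0.50, adjusted p = 0.0277) and Kdm5c (-0.47, adjusted p = 0.0142). Eif2s3x (-0.43, adjusted p = 0.0564), Utp14a (-0.32) and Ddx3x (0.06) did not pass over all genes, although Eif2s3x passed in 10 of 28 alternatives (lowest adjusted p = 0.00117) and Utp14a in 2 (0.00368). The calls of Pin4 and Kdm5c depended on the libraries: over 28 alternatives Pin4's adjusted p ran from 2.73e-05 to 0.215, with the call lost when any of the 9 control libraries was left out, and Kdm5c's from 1.74e-05 to 0.111, with the call lost in 5 leave-one-out fits.

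Apart from the Y and X lists, 4 lists differed between the control groups by camera. Placental prolactins (median 0.25, adjusted p = 0.00167) and the hypoxia response (0.09, 0.0495) were higher in males, and the interferon response (-0.14, 0.00137) and macrophage genes (-0.20, 0.00139) were lower. With an estimated correlation the adjusted p was 0.908, 0.785, 0.908 and 0.762. The prolactin call ended without male control replicate 4 (0.0811), and the interferon call without male control replicate 1 (0.145) or 2 (0.0822). For the hypoxia response, 14 of the 17 libraries ended the call when left out. With male control replicate 4 left out, 10 lists were called in place of 6, and without male control replicate 1 the number was 4.

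**Figure D4:**
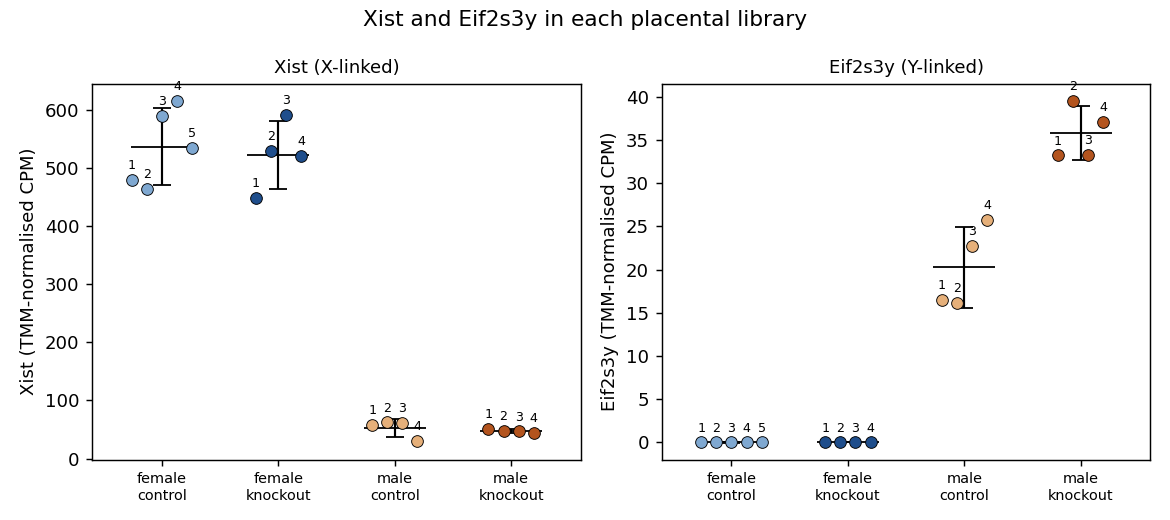
Xist and the Y-linked Eif2s3y in each library, in TMM-normalised CPM on a linear axis, 1 point per library numbered by its replicate, with the mean ± SD of each group as a bar. Xist lies between 447.7 and 615.6 CPM in the 9 female libraries and between 30.33 and 62.27 CPM in the 8 male libraries.

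In the knockouts, 9 genes differed between males and females, the same 5 on the Y chromosome together with Xist (-3.46, SE 0.187), Ogt (-0.69), Taf1 (-0.57) and Pin4 (-0.60), with 2525 at an unadjusted p under 0.05. In a fit on only the groups compared, Ogt, Taf1 and Pin4 lost their calls (adjusted p = 0.12, 0.0689 and 0.628). Male knockouts carried 40.18 CPM of Ddx3y, 35.77 CPM of Eif2s3y, 11.36 CPM of Kdm5d, 9.415 CPM of Uty and 1.797 CPM of Gm29650. Camera called 18 lists. Nutrient transporters (0.31, adjusted p = 3.61e-05), imprinted genes (0.21, 4.06e-06) and syncytiotrophoblast layer II (0.61, 0.0015) were higher in male than in female knockouts, and ribosomal proteins (-0.21, 1.52e-14), oxidative phosphorylation (-0.10, 0.000154) and inflammation genes (-0.18, 0.0089) were lower. These 6 and the Y and X lists kept their calls whichever library was left out. With an estimated correlation the adjusted p was 0.504 for imprinted genes, 0.668 for oxidative phosphorylation and 0.587 for the other 4, and the Y and X lists passed (5.41e-06 and 0.00325). DESeq2 called 63 genes (26 higher and 37 lower). The edgeR count was 32 without female knockout replicate 1 and 15 without male knockout replicate 1, and the list count was 11 without female knockout replicate 2.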

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

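The tests of decidua and yolk sac tissue in female knockouts, both tests of the labels behind Mcu, and the test of female tissue behind Eif2s3y were chosen after the result was seen, and so were the zone balance covariate, its test with direction counted and the counts of splits for lists in the sex-by-genotype, average and sex comparisons and for genes at an unadjusted p under 0.05 in the first 2 of these.

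The first pattern is that gene lists move together in female knockouts, with endothelial, syncytial and erythroid genes lower and ribosomal protein, prolactin and spongiotrophoblast genes higher. For ribosomal proteins, a bias with gene length is argued against as the whole cause: with each library's length trend removed, 79.5% of their female median was left (0.265 before and 0.211 after, 76.5% to 82.8% when each library in turn was left out). The other lists were not part of that test. Their medians went from 0.109 to 0.0552 for oxidative phosphorylation, 0.356 to 0.272 for prolactins and -0.573 to -0.578 for fetal endothelium. Unequal shares of labyrinth and junctional zone in the tissue sampled cannot be told apart from a smaller labyrinth in female knockouts, an effect of genotype that stays open, since both shift the shares alike: with the zone balance score as a covariate, 57% of the mean size of 13 called lists that share no gene with the score was left (0.272 to 0.155, 52.4% to 68.6% leaving out each library), but 2 of them turned sign (chaperones 0.192 to -0.0382, interferon response 0.181 to -0.0616), and with direction counted 51.4% was left (40.4% to 59.3%). The bound on the mean size was set before this test but after the pattern had been seen. It was wrong as an exclusion because it ignores direction. Of the lists without shared genes, erythroid genes went from -0.819 to -0.472 and fetal endothelium from -0.573 to -0.293. More maternal decidua or yolk sac in the knockout tissue cannot be told apart from a change in the placenta, as the larger of both score differences was 0.135 (SE 0.232) for decidua and the yolk sac difference was 0.0856 (SE 0.9), against -0.492 (SE 0.24) for fetal endothelium.

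Chance is not firmly excluded for the number of lists in females. Of 100 splits of the 9 female libraries into 5 and 4, 1 gave as many as 21 called lists, the real one. The highest other gave 20 (median of the others 12), so the real count stands barely above the others. Those lists rest on correlated genes, and even splits without meaning call many. Chance is not excluded either for the 2796 female genes at an unadjusted p under 0.05, as 9 of 100 splits gave as many, up to 5181. For genes called by edgeR in females, in males, in the sex-by-genotype term and on average, the counts of splits decide nothing, because the real count was 0 (DESeq2 33, 0, 0 and 2, limma-voom 0, 2, 0 and 0) and every split gives at least that: 100 of 100, 35 of 35, 100 of 100 and 100 of 100, with 1556, 1, 1409 and 4 in the highest other. The splits with the most called genes in the female, sex-by-genotype and knockout sex comparisons all set female knockout replicates 2, 3 and 4 apart from replicate 1, which points to a structure of these samples: a female split with 1556 put female control replicate 2 with those 3. In males, 33 of 35 splits gave as many as 394 genes at an unadjusted p under 0.05 (highest other 2449) and 11 of 35 as many as 12 lists (highest other 20), so chance is not excluded there. Nor is it for the sex-by-genotype term, where 56 of 100 splits gave as many as 628 such genes (highest other 5349) and 23 of 100 as many as 15 lists (highest other 21). On average over both sexes, 4 of 100 splits gave as many as 18 lists (highest other 19), a share under 5% that lies within the range of the other splits and does not firmly exclude chance, and 6 of 100 as many as 1959 such genes (highest other 3675), which does not exclude it. For sex in controls, 1 of 100 splits gave as many as 10 genes and the highest other gave 1, which excludes chance, while 69 of 100 gave as many as 6 lists (highest other 19), which does not. For sex in knockouts, 3 of 35 splits gave as many as 9 genes (highest other 1567) and 2 of 35 as many as 18 lists (highest other 19), so neither number alone excludes chance. The levels of 5 of those 9 genes do: Ddx3y, Kdm5d, Uty and Gm29650 had 0 counts in all 9 female libraries and were at least 528, 142, 132 and 11.7-fold above the floor of 3 counts in each male library, and Xist ran from 447.7 to 615.6 CPM in females and from 30.33 to 62.27 CPM in males.

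The second pattern is that Mcu of male knockout replicate 2 lies next to the control range, at 35.51 CPM against 18.82 to 28.4 CPM in the other 7 knockouts. A swap with a control library is argued against, since it needs a control among the knockouts and the lowest control stood at 36.7 CPM, above the highest of the other 7 knockouts at 28.4. A control library carrying a knockout label could account for it: its Mcu lay -1.44 SD from the mean of the 9 controls (39.21 ± 2.581 CPM), whereas the nearest other knockout lay -4.189 SD away. Its Eif2s3y, at 39.52 CPM, lay at the top of the knockouts and above every male control (16.2 to 25.7 CPM), which speaks the other way as far as that gene follows genotype. Weaker excision by the recombinase in that placenta stays open as a biological explanation and was not tested.

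The third pattern is that Eif2s3y differs between male libraries, from 16.2 to 25.7 CPM in the 4 controls and from 33.2 to 39.5 CPM in the 4 knockouts. Female tissue mixed into some male libraries is argued against, because it would lower all Y-linked genes alike: the SD over male libraries of log2 Eif2s3y against the other Y-linked genes was 2.25 times that of Kdm5d (0.465 and 0.207). Reads shared between Eif2s3y and its X-linked copy Eif2s3x are argued against too, since the SD of the sum of both genes was 113% of that of Eif2s3y alone (10.2 and 9.09 CPM) and would shrink if reads moved between them. Y chromosomes of different origin in the control and knockout males could give such a difference, and the labels name no strain or sire, so it was not tested. An effect of Mcu loss on this gene stays open as well, and the difference did not pass over all genes in edgeR (adjusted p = 1).

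In 394 tests of a group for a library far from the others (its gap to the nearest, as a share of the group's range, above Dixon's critical value), 20 stood apart (5.08%), and chance gives about 1 in 20, or 19.7. Male control replicate 4 had the most, 4 of them. It had Xist at 30.3 CPM (57.8 to 62.3 in the others of its group), an interferon response score of 4.16 (3.42 to 3.53), a glycolysis score of 6.6 (6.85 to 6.86) and a hypoxia response score of 5.93 (6.27 to 6.29). Among the mitochondrial calcium genes, male control replicate 2 had Micu2 at 32.7 CPM (44.9 to 45.6) and Slc25a23 at 18.8 CPM (11.4 to 12), and male knockout replicate 3 had Smdt1 at 25 CPM (35.5 to 37.4). Male knockout replicate 1 had Pcdh1 at 23.3 CPM (28.4 to 28.7) and Pxt1 at 0.998 CPM (1.38 to 1.43). Female knockout replicate 3 had Dhcr7 at 10.5 CPM (11.8 in the others), and male control replicate 1 had Rhox2a at 1.15 CPM (0.211 to 0.236). Of the scarce transcripts, Gm17182 stood at 0.0413 CPM in male knockout replicate 3 and Gm11826 at 0.783 CPM in male knockout replicate 4. ENSMUSG00000120678 stood at 0.395 CPM in female control replicate 1, 0.0212 CPM in female knockout replicate 2 and 0.413 CPM in male knockout replicate 3. Female control replicate 3 held 1 count of Eif2s3y (0.0149 CPM) where the other female controls held 0, which also put its Y-linked score at -4.62 (-4.75 in the others). The extracellular matrix score of female knockout replicate 4 was 6.88 (7.1 to 7.12), and the sinusoidal giant cell score of female control replicate 4 was 11 (10.8 to 10.9).

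For 15 lists the knockout effect differed between the sexes by camera on the sex-by-genotype term, each given here as the male minus the female effect, in median log2. They were ribosomal proteins (-0.227), nutrient transporters (0.231), fetal endothelium (0.356), imprinted genes (0.145), angiogenesis (0.244), inflammation (-0.209), erythroid genes (0.498), syncytiotrophoblast layer I (0.442) and layer II (0.454), nuclear-encoded oxidative phosphorylation (-0.0746), prolactins (-0.262), yolk sac (-1.38), maternal decidua (-0.417), mitochondrially encoded transcripts (0.0972), and fetal stroma and pericytes (0.162). Their adjusted p ran from 1.49e-15 to 0.0498 with a preset correlation, and was 0.609 or 0.61 with an estimated one. Left-out libraries ended 7 of these calls, for example that of maternal decidua without female knockout replicate 1 (adjusted p = 0.608). For these lists, exact permutation tests of the same term on library scores gave p from 0.0791 (inflammation) to 0.499 (oxidative phosphorylation). With the median of the list as the score, erythroid genes gave exact p = 0.0465 (adjusted p = 0.707). Of the 41 mean scores, only 1 had an exact p under 0.05. That was the Y-linked score (0.251 in males and -0.0242 in females, exact permutation p = 0.0317, adjusted p = 0.794 over 41 scores), a list whose members females do not express.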

How the results depend on the processing

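Each result was recomputed under the alternatives. The zone balance covariate and the removal of gene length trends were added after seeing the data. For genes, DESeq2 called 33 in place of 0 in females, 2 in place of 0 on average and 63 in place of 9 for sex in knockouts, limma-voom with quality weights called 2 in place of 0 in males, and DESeq2 brought Mcu in females (-0.6138, adjusted p = 0.0299) past the threshold. For lists, camera with an estimated correlation called 0 in females, males, the sex-by-genotype term and the average and 2 for sex in controls and in knockouts, and fry called 1, 0, 0, 0, 2 and 2. With the zone balance covariate the lists called were 11 in females, 2 in males, 8 on average and 10 for sex in controls, and with the decidua score 1 in males. The cause was not tested for any of these. An estimated correlation widens the test where it lies above the preset value, which depends on the list. For the lists called in females it lay above, from 0.0907 for fatty acid handling to 0.747 for syncytiotrophoblast layer II. It lay below for mitochondrial calcium (-0.0104), steroidogenesis (-0.018) and labyrinth progenitors (-0.0383), which were not called in females. No called gene named in the text changed sign. Called lists that turned direction, each then without a call, were chaperones, the interferon response, spongiotrophoblast and parietal giant cells in females, nutrient transporters in males, and the interferon response, layer II, spongiotrophoblast and parietal giant cells on average, all with the zone balance covariate, decidua in males and in the sex-by-genotype term with its own score, and oxidative phosphorylation in males without male knockout replicate 4.

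With each library left out in turn, the genes called ranged from 0 to 1083 in females (1083 without female knockout replicate 1, 1 without female control replicate 3), 0 to 0 in males and in the sex-by-genotype term, 0 to 1 on average (1 without male knockout replicate 2), 8 to 11 for sex in controls and 9 to 32 for sex in knockouts. Lists ranged from 13 to 21 in females, 1 to 15 in males, 12 to 18 for the sex-by-genotype term, 15 to 20 on average, 4 to 10 for sex in controls and 11 to 18 for sex in knockouts. Mcu ranged from -0.6681 to -0.4908 in females and from -0.7803 to -0.5193 in males. Mcu in females passed the threshold without female knockout replicate 1 (adjusted p = 0.0315). Over the other named genes and all alternatives, 3915 values kept their direction and side of the threshold, 175 not called in the main analysis changed sign, 43 passed newly and 19 no longer passed.

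The replicate block, which sets libraries with 1 number together, gave 0, 0, 0, 0, 8 and 10 genes and 18, 10, 13, 16, 7 and 17 lists in the order above, with a Mcu log2 fold change in females of -0.5654 and a Mcu log2 fold change in males of -0.6156. Whether knockout and control libraries with 1 number deviate together was checked: the correlation of their residuals was 0.472, -0.112, -0.0651 and -0.11 in females and 0.272, 0.148, -0.13 and 0.173 in males. Of the 8 control libraries that share a number with a knockout, 4 correlated best with the knockout of their own number (female 1 and male 1, 2 and 4), a hint from the data for part of them. As not every pair was above 0.1, the numbers are read as names only.

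No alternative changed the depth, so what it limits was not measured. On simulated counts, the female comparison recovered 44.8% of genes changed 1.5-fold, 80.6% at 2-fold and 93.9% at 3-fold (19351 genes), and the male 40.3%, 85.1% and 95.5% (19375 genes). A simulated change of 1.5-fold was thus missed more often than found. The changed genes all had a mean of at least 1 CPM, so recovery of scarcer genes was not measured. The median SE on the log2 scale was 0.155 in females and 0.164 in males.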

Other observations

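Of these tests, that of Xist was chosen after the result was seen, as was the fit without female knockout replicate 1 for closer description, and the zone balance score in the test of Mcu was defined after the list scores had been seen. Genes of the maternal side of the placenta varied between libraries within each group. In females, 12 of 15 decidua genes were higher in knockouts, with a median log2 fold change of 0.32 that camera did not call (adjusted p = 0.356). The most abundant of them, the decidual prolactin Prl8a2, stood at 334.4 CPM in female controls and 505.5 CPM in female knockouts, and at 380.8 and 279.2 CPM in males. The decidua score was 5.279 in female knockout replicate 1, the highest of all libraries, and 4.703, 4.202 and 4.892 in replicates 2 to 4. Female controls ran from 4.479 to 4.777. Without that replicate the female median was 0.143 (camera adjusted p = 0.596), with 3 decidua genes called lower and 0 higher. Uterine natural killer genes had no settled direction in females (median log2 fold change 0.20, score difference -0.0975, camera adjusted p = 0.974). Yolk sac transcripts varied widely: the yolk sac score ran from 2.255 to 5.725 in the 9 female libraries and from 1.789 to 5.647 in the 8 male libraries.

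In the fit without female knockout replicate 1, insulin and IGF signalling genes, which govern growth, had 6 called members of 31, all lower, while camera did not call the list (median -0.03, adjusted p = 0.211) and fry did (0.0364): Igf2 (-0.77), the receptor Igf2r (-0.32), the growth inhibitor Grb10 (-0.91), Igfbp2 (-0.80), Igfbp3 (-0.52) and Mtor (-0.46). Igf2, Igf2r and Grb10 also stand on the imprinted list and Igfbp3 on the decidua list, so these calls are not separate from those. With all libraries 0 of the 31 insulin and IGF signalling genes passed in edgeR, over the list or over all genes. In that reduced fit Phgdh, the first enzyme of serine synthesis (-1.16), Fabp3, a fatty acid carrier (-0.82), and the endothelial lipase Lipg (-1.22) were lower too, while the chaperone-linked Herpud1 (0.62) and the chemokine Cxcl1 (1.05) were higher. Fry, which makes no comparison with other genes, called 15 lists there in place of 1, and camera with an estimated correlation called 0 (smallest adjusted p = 0.286).

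A hypothesis was that the Mcu transcript left in knockouts tracks the labyrinth share of the library, since the recombinase acts in trophoblast and not in maternal or vascular cells. Over the 8 knockouts, Mcu and the zone balance score gave Pearson r = 0.547 (exact permutation p = 0.164, adjusted 0.246 over 3 relations) and Spearman rho = 0.262 (exact p = 0.536), and r = 0.168 (exact p = 0.817) without the 2 libraries farthest from the median. Over the 9 controls r was -0.328 (exact p = 0.398, adjusted 0.398), rho was -0.1 (exact p = 0.81), and r without 2 libraries was 0.15. The bound set beforehand, a p of 0.05 or more, cannot exclude the idea with so few libraries, because an r of 0.547 stays short of it. The score also sets trophoblast lists against other trophoblast lists and holds no list of maternal or vascular cells. It does not measure the share of cells outside trophoblast on which the stated reason rests, so the question is left open.

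Xist in the male libraries averaged 50.25 ± 10.61 CPM (SD, n = 8), or 9.48% of the 530 ± 59.52 CPM of the female libraries (n = 9). A candidate source is maternal tissue, as the decidua belongs to the dam. Xist correlated with the maternal decidua score over the 8 male libraries (Pearson r = 0.848, exact permutation p = 0.00838, adjusted 0.0251; Spearman rho = 0.905, exact p = 0.00456), and with 6 libraries left after removing the 2 farthest from the median r was 0.809 (exact p = 0.05). Of 15 cell type scores the decidua score ranked 1, before yolk sac (r = 0.699) and uterine natural killer cells (0.678). Of the 15 decidua genes 1 stands on another list, all 15 were tested here, and their levels cannot be given as decidual alone, because trophoblast may express some of them. The ranking was not tested, and male control replicate 4, lowest in Xist at 30.3 CPM, had a decidua score of 4.235, the lowest of the male libraries.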
